A study of Mus musculus with 8 samples.

How the data were processed

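The gene counts used here are as deposited by the authors, 1 file per library with 41388 gene identifiers each. Per the submitters' processing notes, reads were aligned with STAR to GRCm38 and counted per gene with HTSeq 0.5.4, and edgeR 3.12.0 was used; the strand setting and the annotation release are not given in the sources used here. The values are whole numbers and were used as raw counts, with 0 columns of per-sample values left unused. Gene symbols, coordinates, GC content and transcript length came from GENCODE M21: 40254 identifiers matched a symbol, 1134 did not (0.155% of counts), and 1 symbol of the gene lists, Lilrb4a, found no match. Raw reads, sorting data and protein measurements were not analysed here.

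Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1). Genes passed filterByExpr by group with a minimum count of 10, which left 12002, and libraries were scaled by TMM. All 8 libraries entered 1 quasi-likelihood fit (glmQLFit, glmQLFTest; residual degrees of freedom 5, prior degrees of freedom 5.08, common dispersion 0.0223), and each comparison was a contrast of group means. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested; "adjusted p" in the text means this unless camera is named. CPM are relative to the TMM-scaled library size, taken over the tested genes. For the mean log2 CPM scores the scaled library size covers all genes. Group values are mean ± SD over libraries, and SE is that of the fitted log2 fold change. Where a group holds 3 counts or fewer the text gives a ratio from counts with a 95% interval in place of a fitted fold. Where it holds 0 counts the text gives a bound from a floor of 3 counts. As an exception, the folds given with the neutrophil covariate are fitted values for all genes. These intervals and floors cover counting error only. No paired analysis was possible because replicate numbers follow accession order and the labels do not link CD11c+ and CD11c- libraries of the same mouse.

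The 29 gene lists were written before the data were examined: homeostatic microglia, disease-associated microglia, type I interferon response, MHC class II and costimulation, MHC class I presentation, inflammatory cytokines and chemokines, complement and its receptors, growth factors, cell cycle, cholesterol biosynthesis, lipid uptake and efflux, glycolysis, oxidative phosphorylation, lysosome, immediate early and dissociation stress, mitochondrially encoded and sex-linked genes, and markers of monocytes, border-associated macrophages, dendritic cells, neutrophils, T cells, B cells, NK cells, astrocytes, oligodendrocytes, neurons, endothelial cells and erythrocytes. Lists with at least 3 tested members (23 of 29) were tested with camera, a competitive test, at a preset inter-gene correlation of 0.01 and with Benjamini-Hochberg adjustment over lists within a comparison; the text also gives the adjusted p with the correlation estimated from the data. Genes are named by a rule: Itgax, Itgam and Ptprc; the 12 largest log2 fold changes in each direction among called genes at a mean of at least 5 CPM with fully separated groups; up to 4 members per list with the smallest adjusted p; and any member of the homeostatic, disease-associated and growth factor lists. Csf3r, Fpr2, Gda and Slfn4, outside that rule, were chosen after their values were seen. Of the genes that the rule names, 1 is not reported here. Of the tested genes 3361 overlap another coding gene.

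Alternatives were other scalings (RLE, upper quartile, library size only), no or a stricter low-count filter, DESeq2 1.42.0, the edgeR exact test, only the groups compared, a 2-fold threshold and each library left out in turn. Others were chosen after seeing the data: the immediate-early or the neutrophil mean log2 CPM (prior count 2) as a covariate, and a per-library correction for GC content and transcript length, also without each CD11c+ library (99.53% of tested genes have both values). For the shared genes, 50 simulations drew all 8 libraries, controls included, from the control means. Both unchanged groups were compared with the same simulated controls.

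The pipeline was tested on simulated data with genes planted at 1.5, 2 and 4-fold. It recovered 14.9%, 56.7% and 87.9% of them between the NMO subsets, and 25.4%, 70.1% and 89.4% for NMO CD11c- against control. For NMO CD11c+ against control it recovered 11.9%, 59.7% and 86.4%. False calls were 6.61%, 7.30% and 5.17% in the same order. The simulation gave each gene the same dispersion in all groups and no GC trend. Recovery in comparisons that use the CD11c+ libraries may therefore be lower in the real data. The planted list was called in each and 0 of 20 unchanged lists were. The simulated genes varied independently, whereas the correlation estimated within a real list reached 0.922 (immediate-early genes, between the NMO subsets). The simulation therefore does not show how often camera calls unchanged lists of correlated genes. Scripts ran in Python 3.11.15 and R, with figures by matplotlib 3.10.9.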

Results

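Microglia, the resident macrophages of the central nervous system, were sorted by CD11b, CD45 and CD11c from adult C57BL/6 mice. Some mice had neuromyelitis optica (NMO), an inflammatory disease of the central nervous system, and others were controls. Total RNA was sequenced from 8 libraries in 3 groups: CD11c+ microglia of NMO mice (n = 2), CD11c- microglia of NMO mice (n = 3) and control microglia (n = 3). One label gives the control cells as CD11c negative while their titles call them total microglia of unmanipulated mice. Whether CD11c+ cells were removed from the controls is therefore open. The control libraries are numbered 21 to 23 and the NMO libraries between 7 and 12, and the labels give no batch. Any difference in handling or preparation between them cannot be told apart from disease in the comparisons with controls. The libraries hold 4943207 and 5914412 counts for CD11c+ cells, 6437516 to 6819662 for NMO CD11c- cells and 7500815 to 9246061 for controls. Enough counts for a test were found for 12002 genes. The labels do not say that each library came from a separate mouse, so the p-values measure only the spread between these samples. Itgax, which encodes CD11c, was at 185 ± 4.84 CPM (counts relative to the library total, mean ± SD) in the CD11c+ group, 38.9 ± 3.04 in the NMO CD11c- group and 31.2 ± 0.809 in the controls. Ptprc, which encodes CD45, was at 851, 833 and 658 CPM in the same order. Itgam, which encodes CD11b and overlaps another gene model, was at 2218, 2589 and 2349 CPM. Neither Ptprc nor Itgam was called in any comparison with all libraries. Ptprc is called higher in NMO CD11c- than in control cells without CD11c+ replicate 1 (adjusted p = 0.0313) or 2 (0.0281), and in CD11c+ than in control cells without CD11c+ replicate 1 (0.012).

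The first question was how CD11c+ microglia differ from CD11c- microglia within NMO mice. Itgax was higher in the CD11c+ cells by a log2 fold change of 2.25 (SE 0.10, adjusted p = 7.28e-06, n = 2 against n = 3). The gene, ENSMUSG00000030789, lies on chromosome 7 from 128129547 to 128150657 in GRCm38 (GENCODE M21). Chst2, a sulfotransferase of carbohydrate chains, rose from 15.9 ± 1.14 to 46.5 ± 3.52 CPM (log2 fold change 1.55, SE 0.149, adjusted p = 0.00628; control 4.96 CPM; ENSMUSG00000033350, chromosome 9 from 95399292 to 95406722). Clec7a, the beta-glucan receptor dectin-1, rose from 38.1 ± 4.07 to 94.8 ± 16.2 CPM (log2 fold change 1.32, SE 0.162, adjusted p = 0.0151; control 23.8 CPM; ENSMUSG00000079293, chromosome 6 from 129461591 to 129472779). Itgax, Chst2 and Clec7a stay called without each library in turn. Axl, a receptor tyrosine kinase that helps phagocytes take up dying cells, rose from 182 ± 24.6 to 490.4 ± 85.3 CPM (log2 fold change 1.43, SE 0.22, adjusted p = 0.0281; control 52.0 CPM; ENSMUSG00000002602, chromosome 7 from 25757273 to 25788705). The Axl call is lost without CD11c+ replicate 1 (adjusted p = 0.09), NMO CD11c- replicate 1 (0.102) or 3 (0.0605), or control replicate 2 (0.0518) or 3 (0.0777). The largest differences were downward and included genes of the neutrophil marker list. S100a8, a subunit of calprotectin, was at 2.87 ± 1.17 CPM in CD11c+ cells and 847 ± 697 CPM in NMO CD11c- cells (log2 fold change -8.17, SE 0.864, adjusted p = 0.00731; control 182 ± 60.8 CPM; ENSMUSG00000056054, chromosome 3 from 90668978 to 90670035). This call is lost without CD11c+ replicate 1 (log2 fold change -7.83, adjusted p = 0.0745).

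In total 12 genes were higher and 22 lower in CD11c+ than in CD11c- microglia of NMO mice by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. An unadjusted p under 0.05 was found for 1853 genes. Leaving out 1 library moved the counts widely, to 4 higher and 0 lower without CD11c+ replicate 1 (645 lower at unadjusted p under 0.05). They were 1435 and 1581 without CD11c+ replicate 2. Without NMO CD11c- replicates 1, 2 and 3 they were 3 and 16, 17 and 62, and 10 and 68. Without control replicates 1, 2 and 3 they were 10 and 20, 4 and 7, and 5 and 17. With library size alone as scaling the split was 8 higher and 24 lower. CD11c+ replicate 1 departs from the other libraries with gene GC content (Spearman correlation over genes 0.592, others -0.299 to -0.0378). After correction for GC content and length 25 genes are higher and 28 lower.

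Of the 27 tested genes of disease-associated microglia 3 were higher, Clec7a, Axl and Cst7, and 13 were higher and 1 lower when adjusted over the list alone. The list median of log2 fold change was 0.49 (camera adjusted p = 2.3e-12, adjusted p = 0.00978 with an estimated correlation). Cst7, the protease inhibitor cystatin F, was at 38.4 ± 3.47 against 14.6 ± 3.70 CPM (log2 fold change 1.40, SE 0.234, adjusted p = 0.0466; control 5.23 CPM). The Cst7 call is lost without CD11c+ replicate 1 (adjusted p = 0.117), NMO CD11c- replicate 1 (0.121) or 3 (0.0739), or control replicate 1 (0.0915), 2 (0.0638) or 3 (0.0595). Gpnmb, a glycoprotein of lipid-laden phagocytes, did not pass (6.50 against 1.29 CPM, log2 fold change 2.32, SE 0.465, adjusted p = 0.0662), though it does without CD11c+ replicate 2 (0.0234). On leaving out CD11c+ replicates 1 and 2, NMO CD11c- replicates 1, 2 and 3 and control replicates 1, 2 and 3 in turn, the number of higher list members went from 3 to 2, 12, 1, 4, 1, 2, 1 and 1.

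Of the 10 tested neutrophil genes 9 fell, and the same 9 fell when adjusted over the list alone. Csf3r, which microglia also express, did not pass and was at 1357, 1218 and 1043 CPM in CD11c+, NMO CD11c- and control cells. The list median was -8.24, or -7.73 with the genes at 0 counts placed at their bound (camera adjusted p = 1.63e-47, adjusted p = 0.0125 with an estimated correlation). S100a9, the partner of S100a8, was at 4.10 ± 1.18 against 1550 ± 1410 CPM (log2 fold change -8.54, SE 0.924; control 333.8 ± 111 CPM). Mmp9, a gelatinase, was at 0.687 against 76.4 ± 17.5 CPM (log2 fold change -6.81, SE 0.726; control 28.9 CPM). Ly6g, the neutrophil surface antigen, was at least 56.2-fold lower. Without CD11c+ replicate 1 none of these genes is called (S100a9 and Mmp9 adjusted p = 0.0745). The mean log2 CPM of the neutrophil genes was 0.883 and 1.22 in the CD11c+ libraries, 6.59 to 7.85 in the NMO CD11c- libraries and 5.10 to 6.28 in the controls. These genes thus set the CD11c+ libraries apart from the other groups, with or without disease. Of 12 monocyte genes 2 fell, among them Chil3, which neutrophils also express, and 6 fell when adjusted over the list alone. Their median was -0.79 (camera adjusted p = 3e-08, adjusted p = 0.0453 with an estimated correlation, which becomes 0.0835 after GC and length correction). With CD11c+ replicates 1 and 2, NMO CD11c- replicates 1, 2 and 3 and control replicates 1, 2 and 3 left out in turn, 0, 9, 7, 9, 9, 9, 6 and 9 neutrophil genes and 0, 3, 1, 3, 3, 2, 0 and 1 monocyte genes were lower.

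Between the subsets the type I interferon list was level by camera (median log2 fold change 0.10, adjusted p = 0.349). Of its 26 genes 0 were called by edgeR quasi-likelihood, 0 by DESeq2 and 0 by the exact test, with 1 higher and 1 lower at unadjusted p under 0.05. That list is called higher without CD11c+ replicate 1 (adjusted p = 0.00801) or NMO CD11c- replicate 2 (adjusted p = 0.00825). MHC class I genes had a median of 0.41 (camera adjusted p = 7.05e-07, adjusted p = 0.115 with an estimated correlation). Of these 12 genes 0 were called by edgeR quasi-likelihood, 3 by DESeq2, 3 by the exact test, 7 at unadjusted p under 0.05 and 7 when adjusted over the list alone. Growth factor genes had a median of 0.31 (camera adjusted p = 0.0027, adjusted p = 0.0885 with an estimated correlation). Of these 16 genes 0 were called by edgeR quasi-likelihood, 1 by DESeq2, 0 by the exact test, 7 at unadjusted p under 0.05 and 3 when adjusted over the list alone. The homeostatic microglia list had a median of -0.16 (camera adjusted p = 0.0339, adjusted p = 0.735 with an estimated correlation). Its camera call is lost without CD11c+ replicate 2 (0.328) or NMO CD11c- replicate 1 (0.255) or 3 (0.13). Of its 22 genes 0 were called by edgeR quasi-likelihood, 0 by DESeq2 and 0 by the exact test, with 5 lower at unadjusted p under 0.05. Without CD11c+ replicate 2 calls do appear in these lists, 1 lower for interferon, 8 higher for MHC class I, 5 higher for growth factors, and 5 lower and 1 higher for homeostatic genes. Without CD11c+ replicate 1 a growth factor gene is called, and after GC and length correction the MHC class I list has adjusted p = 0.0388 with an estimated correlation.

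**Figure D1:**
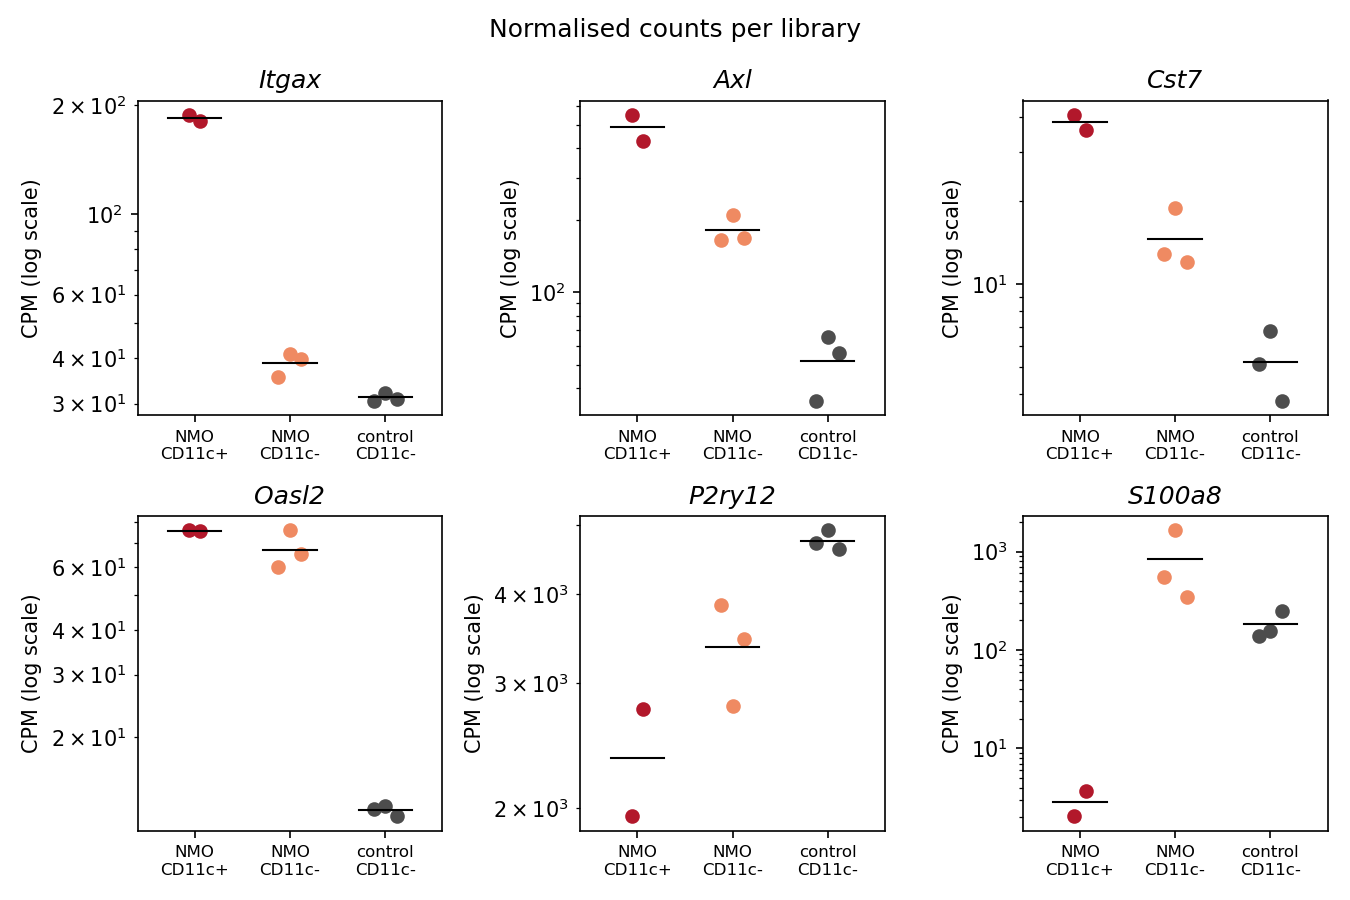
CPM of Itgax, Axl, Cst7, Oasl2, P2ry12 and S100a8 in each of the 8 libraries on a logarithmic axis, each point 1 library and each line a group mean. Axl is at 490.4, 182 and 52.0 CPM and S100a8 at 2.87, 847 and 182 CPM in the NMO CD11c+, NMO CD11c- and control groups.

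The second question was what differs between CD11c- microglia of NMO mice and control microglia. Interferon-stimulated genes rose. Oasl2, of the antiviral oligoadenylate synthetase family, went from 12.5 ± 0.421 to 67.0 ± 8.24 CPM (log2 fold change 2.42, SE 0.118, adjusted p = 1.76e-05, n = 3 and n = 3; ENSMUSG00000029561, chromosome 5 from 114896936 to 114912234). Slfn5, a schlafen family gene, went from 12.3 to 52.5 CPM (log2 fold change 2.09, SE 0.121, adjusted p = 3.41e-05). Complement C4b, whose product marks targets for phagocytes, rose from 15.9 ± 3.52 to 118 ± 13.3 CPM (log2 fold change 2.89, SE 0.157, adjusted p = 2.59e-05; ENSMUSG00000073418, chromosome 17 from 34728380 to 34743882). The T cell chemoattractant Ccl5 rose from 0.979 ± 0.412 to 10.5 ± 2.80 CPM (log2 fold change 3.43, SE 0.377, adjusted p = 0.000979; ENSMUSG00000035042, chromosome 11 from 83525778 to 83530518). The acute-phase gene Saa3 was at 28.7 ± 10.6 against 0.0765 CPM (ratio from counts 362, interval 99.7 to 2990, adjusted p = 0.000147). Axl rose from 52.0 ± 15.1 to 182 ± 24.6 CPM (log2 fold change 1.80, SE 0.209, adjusted p = 0.0014). All of these genes stay called without each library in turn. Itgax did not pass (31.2 against 38.9 CPM, log2 fold change 0.32, SE 0.0948, adjusted p = 0.101), though it does without CD11c+ replicate 1 (0.0433) or 2 (0.0413).

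In total 360 genes were higher and 86 lower in NMO CD11c- than in control microglia by edgeR quasi-likelihood, of which 193 and 17 changed at least 2-fold. Without CD11c+ replicates 1 and 2 the counts were 788 and 405, and 780 and 401. Without NMO CD11c- replicates 1, 2 and 3 they fell to 204 and 33, 158 and 30, and 326 and 41. Without control replicates 1, 2 and 3 they fell to 123 and 18, 147 and 23, and 145 and 27. The neutrophil marker list had a median log2 fold change of 1.86 here (camera adjusted p = 7.22e-08, adjusted p = 0.136 with an estimated correlation). These counts therefore need not reflect microglia alone.

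Of 26 interferon genes 24 rose, 26 when adjusted over the list alone. Their median log2 fold change was 1.99 (camera adjusted p = 1.68e-106, adjusted p = 0.00985 with an estimated correlation). The antiviral gene Oas2 was at 71.0 ± 16.4 against 10.4 CPM, and the nucleic acid sensor gene Zbp1 had a log2 fold change of 2.57 (SE 0.172). Of 27 disease-associated genes 12 rose, 16 when adjusted over the list alone. The median was 0.68 (camera adjusted p = 3.39e-15, adjusted p = 0.00589 with an estimated correlation). Among them were the cholesterol hydroxylase Ch25h (8.91 ± 1.94 against 0.756 ± 0.659 CPM, log2 fold change 3.47, SE 0.451) and osteopontin, Spp1 (34.0 ± 4.61 against 9.47 ± 3.28 CPM, log2 fold change 1.84, SE 0.242). Of 12 MHC class I genes 6 rose, 9 when adjusted over the list alone, with a median of 0.68 (camera adjusted p = 1.53e-14, adjusted p = 0.0426 with an estimated correlation). B2m, the light chain of class I, was at 2333 ± 8.61 against 1353 ± 81.0 CPM (log2 fold change 0.79, SE 0.119). Of 12 monocyte genes 5 rose, 10 when adjusted over the list alone, with a median of 1.77 (camera adjusted p = 5.25e-13, adjusted p = 0.017 with an estimated correlation). Fibronectin, Fn1, was at 35.3 ± 9.82 against 4.19 CPM (log2 fold change 3.07, SE 0.245). Upon leaving out CD11c+ replicates 1 and 2, NMO CD11c- replicates 1, 2 and 3 and control replicates 1, 2 and 3 in turn, 14, 14, 8, 7, 10, 4, 6 and 5 disease-associated genes and 5, 5, 3, 3, 6, 2, 3 and 3 monocyte genes were called higher. The interferon count stayed between 19 and 26.

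Downward changes in NMO CD11c- microglia were fewer. Gadd45g, a stress-induced growth arrest gene, was at 26.2 against 57.1 CPM (log2 fold change -1.13, SE 0.151, adjusted p = 0.00295). The semaphorin gene Sema4b was at 27.5 against 66.5 CPM (log2 fold change -1.27, SE 0.183, adjusted p = 0.00483), and both calls hold without each library in turn. Of 20 immediate-early and stress genes 3 fell, 6 when adjusted over the list alone, with a median of -1.19 (camera adjusted p = 2.68e-08, adjusted p = 0.355 with an estimated correlation). Genes of this kind respond to cell isolation, and their mean log2 CPM ranged from 6.87 to 8.67 in NMO CD11c- libraries and from 9.14 to 9.99 in controls. Of 22 homeostatic genes 2 fell, and 2 when adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.00111, adjusted p = 0.372 with an estimated correlation). P2ry13, a purinergic receptor gene, was at 992 against 1583 CPM (log2 fold change -0.67, SE 0.139, adjusted p = 0.0272). The P2ry13 call is lost without NMO CD11c- replicate 2 (0.0945) or 3 (0.0932) or control replicate 1 (0.11), 2 (0.12) or 3 (0.0837). P2ry12 did not pass (3367 against 4748 CPM, log2 fold change -0.50, SE 0.159, adjusted p = 0.125), though it does without CD11c+ replicate 1 (0.0276) or 2 (0.025). After leaving out CD11c+ replicates 1 and 2, NMO CD11c- replicates 1, 2 and 3 and control replicates 1, 2 and 3 in turn, 7, 7, 0, 2, 0, 0, 0 and 0 immediate-early and stress genes and 4, 5, 1, 0, 0, 0, 0 and 0 homeostatic genes were called lower.

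The third question was what differs between CD11c+ microglia of NMO mice and control microglia. Subset and disease change together here because no CD11c+ control is among the libraries. Axl rose from 52.0 ± 15.1 to 490.4 ± 85.3 CPM (log2 fold change 3.24, SE 0.23, adjusted p = 4.21e-05, n = 2 against n = 3). Apoe, the lipid carrier, rose from 631 ± 207 to 3956 ± 1980 CPM (log2 fold change 2.65, SE 0.335, adjusted p = 0.00122; ENSMUSG00000002985, chromosome 7 from 19696109 to 19699188). Cst7 rose from 5.23 to 38.4 CPM (log2 fold change 2.86, SE 0.249, adjusted p = 0.000153; ENSMUSG00000068129, chromosome 2 from 150570415 to 150578944). Oasl2 rose from 12.5 to 75.8 ± 0.288 CPM (log2 fold change 2.60, SE 0.127, adjusted p = 5.92e-06) and C4b from 15.9 to 119.8 CPM (log2 fold change 2.91, SE 0.167, adjusted p = 1.51e-05). P2ry12, the ADP receptor that guides microglial processes, fell from 4748 ± 149 to 2355 ± 573 CPM (log2 fold change -1.01, SE 0.184, adjusted p = 0.0086; ENSMUSG00000036353, chromosome 3 from 59216272 to 59262871). Its gene coordinates overlap those of Med12l, and whether this affects the assignment of its reads was not checked. These calls hold without each library in turn.

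In total 822 genes were higher and 403 lower in CD11c+ than in control microglia by edgeR quasi-likelihood, of which 351 and 84 changed at least 2-fold. Without CD11c+ replicates 1 and 2 the counts were 651 and 227, and 2019 and 2058. Without NMO CD11c- replicates 1 and 3 they were 615 and 229, and 598 and 212. Without control replicates 1, 2 and 3 they were 398 and 117, 414 and 110, and 385 and 102.

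Of 27 disease-associated genes 17 rose in CD11c+ microglia, 23 when adjusted over the list alone. The median log2 fold change was 1.12 (camera adjusted p = 3.21e-27, adjusted p = 0.00139 with an estimated correlation). Gpnmb was at 6.50 against 0.561 CPM (log2 fold change 3.50, SE 0.505) and Lpl, the lipoprotein lipase, at 157 against 77.7 CPM (log2 fold change 1.02, SE 0.156). Of 26 interferon genes 22 rose, 26 when adjusted over the list alone, with a median of 1.97 (camera adjusted p = 1.8e-63, adjusted p = 0.0238 with an estimated correlation). Of 12 MHC class I genes 10 rose, 11 when adjusted over the list alone, with a median of 1.02 (camera adjusted p = 1.75e-20, adjusted p = 0.0238 with an estimated correlation). H2-D1, a classical class I gene, was at 2226 against 567 CPM (log2 fold change 1.97, SE 0.173). H2-Q7 was at 78.7 against 4.74 CPM (log2 fold change 4.06, SE 0.201), but it has near-identical paralogs and the assignment of reads among them is uncertain. Of 12 MHC class II genes 7 rose, 8 when adjusted over the list alone, with a median of 1.05 (camera adjusted p = 3.17e-07, adjusted p = 0.0238 with an estimated correlation). The invariant chain gene Cd74 was at 223 ± 4.94 against 69.0 ± 16.6 CPM (log2 fold change 1.69, SE 0.209). The MHC class II count is 4 without NMO CD11c- replicate 1 or 3 or control replicate 2 or 3.

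Growth factor genes changed in CD11c+ microglia against controls, where 5 of 16 rose and 1 fell, 8 and 1 when adjusted over the list alone. The list median was 0.22 (camera adjusted p = 0.000556, adjusted p = 0.0446 with an estimated correlation, which becomes 0.0544 after GC and length correction). The lower call is lost without control replicate 2, and 2 are lower without CD11c+ replicate 1. Csf1, the microglial survival factor, rose from 50.1 to 127 ± 35.8 CPM (log2 fold change 1.35, SE 0.163, adjusted p = 0.000964). Pdgfa, a mitogen of oligodendrocyte precursors, rose from 22.5 to 44.3 CPM (log2 fold change 0.98, SE 0.13, adjusted p = 0.00156) and Spp1 from 9.47 to 50.6 ± 14.9 CPM (log2 fold change 2.42, SE 0.26, adjusted p = 0.000551). All 3 stay called without each library. Igf1 did not pass (6.68 against 2.81 CPM, log2 fold change 1.23, SE 0.374, adjusted p = 0.0627), though it does without control replicate 2 (0.0343). Of 22 homeostatic genes 7 fell, 12 when adjusted over the list alone, with a median of -0.39 (camera adjusted p = 0.000129, adjusted p = 0.369 with an estimated correlation). P2ry13 was at 807 ± 58.9 against 1583 ± 90.8 CPM (log2 fold change -0.97, SE 0.159). The homeostatic count is 4 without NMO CD11c- replicate 1 or 3 or control replicate 1 or 3, and 3 without control replicate 2. Of 10 neutrophil genes 9 were lower than in controls, and 9 were lower and 1 higher when adjusted over the list alone. Their median was -6.16, or -6.02 at the bound (camera adjusted p = 1.37e-15, adjusted p = 0.0498 with an estimated correlation, which becomes 0.0544 after GC and length correction), with S100a8 at -5.95 (SE 0.819).

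**Figure D2:**
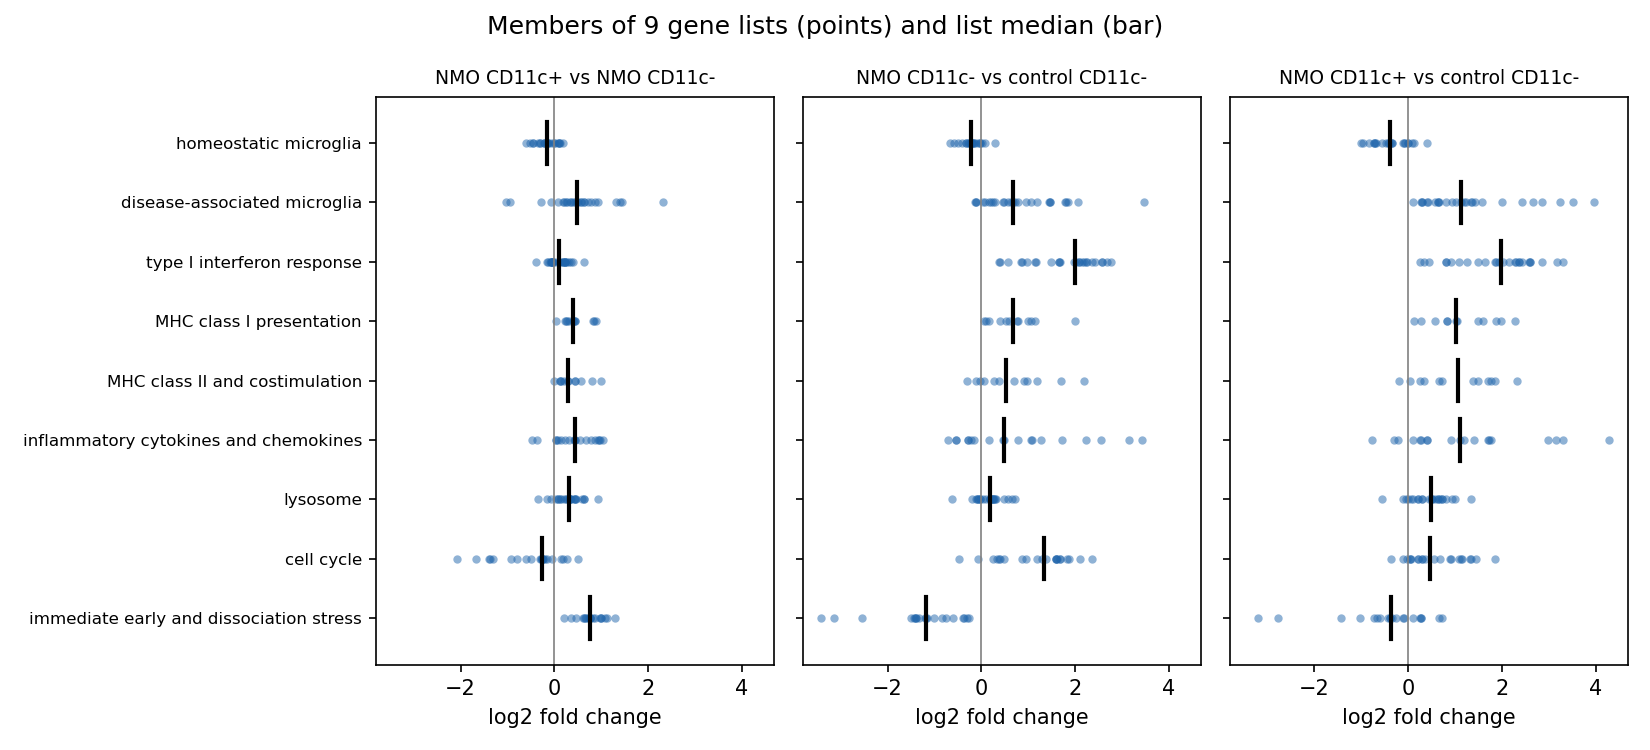
Log2 fold change of the tested members of 9 gene lists in the 3 comparisons, each point a gene and each bar the list median. The interferon median is 0.10 between the NMO subsets, 1.99 for NMO CD11c- and 1.97 for NMO CD11c+ microglia against controls.

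Some of the genes called against controls were the same in both NMO subsets. In each, 276 genes rose and 62 fell, against 24.7 and 2.89 for lists drawn independently, while 6 were called in opposite directions. The same controls enter both comparisons, and 3 libraries cannot be divided between the comparisons with replication, so part of this excess may come from shared controls. In 50 simulations of unchanged groups against shared simulated controls at most 1 gene was shared in each direction. Those simulations call at most 2 genes per direction in each comparison, so they do not show how far shared controls raise the overlap of longer lists. Over all genes the correlation of the 2 comparisons was 0.282, below the median of 0.405 in the simulations, while their covariance was 0.0991 against 0.0309. The total of 338 shared genes became 548 and 714 without CD11c+ replicates 1 and 2. It fell to 203, 168 and 225 without NMO CD11c- replicates 1, 2 and 3, and to 133, 154 and 144 without control replicates 1, 2 and 3. Of the 276 shared higher genes 7 were also higher in CD11c+ than in CD11c- cells of NMO mice. Axl, Cst7 and Clec7a are among them, with means that step up from control to NMO CD11c- to NMO CD11c+ microglia. For NMO CD11c- against control the Cst7 call is lost without control replicate 1 (adjusted p = 0.0556). The Clec7a call there is lost without NMO CD11c- replicate 1 (0.122) or 2 (0.139) or control replicate 1 (0.163), 2 (0.102) or 3 (0.0942). Another 546 genes were called higher than controls in the CD11c+ subset alone. Only 5 of them differed between the subsets when compared directly, so most of that set is not shown to belong to CD11c+ cells.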

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

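The tests of expression that starts with disease, of lower depth and of monocytes, and the covariate and GC corrections, were chosen after results were seen. The value that stands out most is the neutrophil list, whose median log2 fold change between CD11c+ and CD11c- microglia of NMO mice is -8.24, against 1.86 for NMO CD11c- and -6.16 for NMO CD11c+ microglia relative to controls. Single genes have the same shape, each tested by the direct contrast of the subsets. They are S100a8 (log2 fold change -8.17, adjusted p = 0.00731; 2.22 and -5.95 against controls), Gda (-5.48; 1.92 and -3.56), Slfn4 (-4.93; 1.77 and -3.16) and Cxcr2 (-4.63; 1.93 and -2.70). From counts, the CD11c- level is 232 times the CD11c+ level for Hp (interval 79.1 to 1120) and 59.1 times for Fpr2 (interval 16.2 to 491). In each case the NMO CD11c- mean is above that of controls and the CD11c+ mean far below both. The falls below controls of Gda, Slfn4, Cxcr2, Hp and Fpr2 have adjusted p = 0.0366, 0.0289, 0.0411, 0.0315 and 0.0467. By adjusted p the rise over controls is less certain than the fall for S100a8 (0.0377 against 0.00183). It is not less certain for Fpr2 (0.0448 against 0.0467) or Cxcr2 (0.0193 against 0.0411). For S100a8 the rise is not called without NMO CD11c- replicate 1 (0.0537) or 2 (0.0554, log2 fold change 1.31). It is also not called without control replicate 1 (0.185), 2 (0.169) or 3 (0.0905). For Cxcr2 it is not called without NMO CD11c- replicate 1 (0.0593) or 2 (0.0674) or control replicate 1 (0.0627) or 2 (0.092). Hp, Fpr2, Gda and Slfn4 lie near the threshold there (adjusted p = 0.0472, 0.0448, 0.0433 and 0.0472), and the neutrophil list median is 1.20 at its lowest with 1 library left out.

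For the low neutrophil transcripts of CD11c+ cells, neutrophils among the sorted CD11c- cells may be the source. Over the 6 NMO CD11c- and control libraries most markers rise and fall together (median correlation with the other markers 0.866, 0.994 for Ly6g). However, Mmp8 (0.611), Retnlg (0.413) and Csf3r (-0.779) follow the rest less or not at all. NMO CD11c- replicate 2 has the highest neutrophil score of these libraries (7.85), and how far the correlation rests on it was not tested. A programme that starts with disease is argued against by controls holding 27.6% of the NMO CD11c- level (median over markers). A rise with disease above the control level is not excluded by this. Lower depth is argued against because S100a8 and S100a9 together reach at most 2.29% of the count that depth alone would leave. Neutrophil genes switched off within CD11c+ microglia were not tested and stay open, as co-variation of markers would also follow from a shared programme.

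The type I interferon list is higher in both NMO groups than in controls. With the immediate-early score as covariate the median log2 fold change of NMO CD11c- against control is 2.03. That score ran from 6.87 to 8.67 in NMO CD11c- and from 9.14 to 9.99 in control libraries. As the ranges do not overlap, this covariate cannot decide on an immediate-early state of the cells. Scaling is argued against, with a lowest median of 2 over the other scalings. Monocytes among the sorted cells could contribute in NMO CD11c- libraries, where monocyte markers have a median of 1.77 and the test cannot tell; several of those markers are also neutrophil genes. In NMO CD11c+ libraries the monocyte median is 0.269, but members run from -6.93 to 2.46 and the neutrophil genes among them fall there, so this value does not argue against monocytes either. An interferon response of microglia in this disease stays open as the biological reading, since no cell-by-cell data were held. Handling or preparation that differed between NMO and control libraries was not tested and stays open too.

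Few genes are called between the NMO subsets, 34, and 3 technical readings each raise the number: 53 after correction for GC content and length, 182 with the immediate-early score as covariate, and 3016 without CD11c+ replicate 2. The last number rests on CD11c+ replicate 1 alone, the library with the GC trend. Far fewer genes are called without that library, and fewer also when GC correction is added to the omission of replicate 2. The 2 CD11c+ libraries also have the lowest rank correlation of any pair within a group (0.968, others 0.985 to 0.994). They differ both in GC trend (0.592 and -0.0849) and in immediate-early score (7.13 and 9.74), so the 3 readings cannot be told apart. Disagreement between the CD11c+ libraries therefore may hide differences between subsets, and which of the 2 libraries is closer to CD11c+ microglia in general stays open, as does a true difference between the sorted samples.

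For NMO CD11c- against control, the 6 libraries can be divided into 3 and 3 in 10 ways, which cannot give a share under 0.05. The real division calls 446 genes and the highest other 0, so 1 of 10 reaches the real result. For lists, by camera at the preset correlation, it calls 14 and the other divisions 8 to 13, again 1 of 10. The number of lists called at that correlation thus barely sets the real division apart from mixed ones. Every other division mixes NMO and control libraries on both sides, so any disease difference becomes spread within the groups compared. The 0 therefore does not show what unchanged groups would give.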

How the results depend on the processing

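The covariate and GC corrections in this part, and the wider combinations, were chosen after results were seen. The cause of each shift was not tested. Counts are genes higher and lower. Between the NMO subsets (12 and 22 as reported) they were 264 and 443 with no low-count filter, where the prior degrees of freedom rise to 125. They were 107 and 161 by DESeq2, 61 and 127 by the exact test, and 2 and 3 with only the groups compared. They were 80 and 102 with the immediate-early covariate, 0 and 0 with the neutrophil covariate (274 and 62 at unadjusted p under 0.05). After GC and length correction they were 25 and 28, after that correction 5 and 0 without CD11c+ replicate 1 (719 lower at unadjusted p under 0.05) and 356 and 270 without CD11c+ replicate 2. For NMO CD11c- against control (360 and 86) they were 841 and 316 with no filter, 559 and 137 by DESeq2, 1038 and 558 by the exact test, and 803 and 418 with only the groups compared. They were 21 and 0 with the neutrophil covariate (177 lower at unadjusted p under 0.05) and 705 and 235 after GC correction. They were 946 and 476 and 949 and 481 after that without CD11c+ replicate 1 or 2, and 193 and 17 at 2-fold. For NMO CD11c+ against control (822 and 403) 1083 were lower with no filter and 628 by DESeq2. Calls were 466 and 161 with only the groups compared, 2 and 0 with the neutrophil covariate (133 lower at unadjusted p under 0.05), 1267 and 966 after GC correction without CD11c+ replicate 2, and 351 and 84 at 2-fold. Leaving out 1 library gave 3 to 1435 and 0 to 1581, 123 to 788 and 18 to 405, and 385 to 2019 and 102 to 2058 in the same order, and 7 to 14 lists between the subsets. Without 1 CD11c+ library the other is assumed to vary like the other groups. Camera with an estimated correlation called 3, 4 and 7 lists, and list members adjusted over the list alone were 47 and 127 in the first comparisons. The 338 shared genes became 155 at 2-fold, 600 with no filter, 672 by the exact test, 0 with the neutrophil covariate, 658 after GC correction, 664 and 785 after it without CD11c+ replicate 1 or 2, and 133 to 714 with 1 library left out.

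The sign turned in these cases. The neutrophil score nearly divides CD11c+ from CD11c- libraries (0.883 and 1.22 against 5.10 to 7.85), so as a covariate it takes up that contrast. The score is also higher in NMO CD11c- (6.59 to 7.85) than in control libraries (5.10 to 6.28). Score and group therefore cannot be fully told apart there either. With this covariate, between the subsets, the list medians were 0.109 for neutrophils, 2.79 for cell cycle, -0.635 for lysosome, 1.79 for monocytes and 2.09 for border-associated macrophages. Log2 fold changes were -0.007921 for Cd22, 2.003 for Cd177, 1.84 for Anxa1, 2.23 for Lcn2, and 1.29 for Hp. They were 1.37 for Ltf, 0.30 for S100a8, 2.05 for Ngp, 0.74 for S100a9, 1.97 for Chil3 and 0.80 for Camp. For NMO CD11c- against control it gave -0.0333 for the neutrophil list, -0.197 for oligodendrocytes and -0.10 for S100a8. For NMO CD11c+ against control it gave 0.202 for the neutrophil list, -0.0392 for lysosome, -0.09252 for Fn1, -0.29 for Ank, -0.45 for Ctsl, -0.11 for Tyrobp, and -0.38 for Ctsd. It gave 1.17 for Hspa1b, 2.39 for Itgb2l, 1.68 for Lcn2, 1.08 for Hp, 0.82 for Ltf, 0.20 for S100a8, 1.23 for Ngp, 0.38 for S100a9, 0.21 for Camp and 1.08 for Chil3. With the immediate-early covariate the immediate-early list itself was at 0.0497 for NMO CD11c- and 0.199 for NMO CD11c+ against control, and border-associated macrophages at -0.0183 in the latter. With 1 library left out, between the subsets the cytokine median ranged from -0.598 to 0.978 and the immediate-early median from -0.848 to 1.47. For NMO CD11c+ against control the immediate-early median ranged from -2.06 to 0.422, Cd9 from -0.56 to 0.55 and Xist from -0.66 to 0.49. The ends of these ranges are the omissions of the CD11c+ libraries. Cytokines against control ranged from -0.0668 without CD11c+ replicate 2 to 1.65. Border-associated macrophages ranged from -0.496 to 0.385 between the subsets and from -0.261 to 1.12 against control, lowest without CD11c+ replicate 1. After GC correction without CD11c+ replicate 2 cytokines were at -0.378 and immediate-early genes at -1.08 between the subsets, and against control cytokines were at -0.0709 and Cd9 at -0.51. After GC correction without CD11c+ replicate 1 border-associated macrophages were at -0.552 between the subsets. For NMO CD11c+ against control that setting gave -0.257 for border-associated macrophages, -0.00143 for complement and 0.395 for the immediate-early list.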

Other observations

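No test in this part was chosen after results were seen, but the genes of its last paragraph were. In NMO CD11c- against control microglia, chemokine and cytokine genes rose, 6 of 19, and 9 were higher and 1 lower when adjusted over the list alone (median log2 fold change 0.48, camera adjusted p = 4.16e-06, adjusted p = 0.355 with an estimated correlation). In CD11c+ cells 8 of 19 rose, 10 when adjusted over the list alone (median 1.11, adjusted p = 5.83e-07, adjusted p = 0.369 with an estimated correlation). Without CD11c+ replicate 2 that median is -0.07 and adjusted p = 0.164. Cxcl16, a chemokine that also acts as a scavenger receptor, was at 45.0, 94.1 and 149 CPM in control, NMO CD11c- and NMO CD11c+ cells (log2 fold change against control 1.06, SE 0.11, adjusted p = 0.000752, and 1.73, SE 0.12, adjusted p = 4.13e-05). Complement had 1 gene called, C4b, in each comparison with controls (medians 0.16 and 0.36; adjusted p = 5.15e-05 and 0.00134; adjusted p = 0.0697 and 0.124 with an estimated correlation). Lipid uptake and efflux rose in both (4 of 14, median 0.45, adjusted p = 3.81e-06; 5 of 14, median 0.63, adjusted p = 5.54e-06; adjusted p = 0.0515 and 0.0446 with an estimated correlation). MHC class II genes had 2 of 12 called in NMO CD11c- cells (median 0.54, adjusted p = 0.000271, adjusted p = 0.0697 with an estimated correlation). Between the subsets their median was 0.29 (adjusted p = 0.000627, adjusted p = 0.0885 with an estimated correlation). Without CD11c+ replicate 2 that adjusted p = 0.0669. On leaving out CD11c+ replicates 1 and 2, NMO CD11c- replicates 1, 2 and 3 and control replicates 1, 2 and 3 in turn, the higher members in NMO CD11c- cells were 9, 9, 4, 3, 5, 3, 3 and 3 for cytokines, 3, 3, 1, 1, 2, 1, 1 and 1 for complement, 7, 7, 2, 3, 3, 0, 3 and 0 for lipid uptake, and 5, 5, 2, 0, 1, 0, 2 and 0 for MHC class II. In CD11c+ cells they were 12, 7, 7, 7, 8, 5, 5 and 4 for cytokines and 5, 7, 5, 5, 4, 3, 5 and 3 for lipid uptake, and 5 complement genes were higher without CD11c+ replicate 2.

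Lysosomal genes rose in CD11c+ cells against controls, 12 of 24 (median 0.49, adjusted p = 1.11e-05, adjusted p = 0.311 with an estimated correlation). Cd63, a tetraspanin of late endosomes, was at 193 against 75.9 CPM (log2 fold change 1.34, SE 0.158). In NMO CD11c- cells 3 of 24 rose (median 0.18, adjusted p = 0.0323, adjusted p = 0.507 with an estimated correlation). The list call is lost without NMO CD11c- replicate 1 (0.114) or 3 (0.132) or control replicate 3 (0.262). Between the subsets the lysosome median was 0.32 (adjusted p = 0.000145, adjusted p = 0.459 with an estimated correlation). Cell cycle genes rose in NMO CD11c- cells against controls, 4 of 22 and 13 when adjusted over the list alone (median 1.33, adjusted p = 2.31e-08, adjusted p = 0.329 with an estimated correlation). Cdk1, the mitotic kinase, was at 10.0 ± 2.80 against 2.83 CPM (log2 fold change 1.82, SE 0.256, adjusted p = 0.00404). Mki67, a proliferation marker, was at 92.6 CPM in NMO CD11c- replicate 2 and at 37.9 and 32.0 in the other replicates, and its call is lost without control replicate 1 (0.159), 2 (0.153) or 3 (0.0874). In the same comparison 5 of 12 monocyte markers (median 1.77) and 2 of 10 neutrophil markers (median 1.86, adjusted p = 7.22e-08, adjusted p = 0.136 with an estimated correlation) were called higher. Replicate 2 is also highest in the neutrophil genes Ngp and Camp, so which cells carry the cell cycle transcripts is open. In CD11c+ cells 1 rose (median 0.46, adjusted p = 0.0301, adjusted p = 0.635 with an estimated correlation), a list call lost without CD11c+ replicate 1 (0.125) or 2 (0.164). Between the subsets the cell cycle median was -0.27 (adjusted p = 0.0177, adjusted p = 0.735 with an estimated correlation), lost without CD11c+ replicate 2 (0.384) or NMO CD11c- replicate 2 (0.475). With libraries left out in the order given above, higher lysosomal members were 7, 16, 8, 12, 8, 6, 5 and 4 in CD11c+ cells and 5, 6, 0, 0, 0, 0, 0 and 0 in NMO CD11c- cells. Higher cell cycle members were 0, 3, 1, 3, 1, 0, 0 and 0 in CD11c+ cells and 8, 8, 4, 3, 8, 1, 1 and 1 in NMO CD11c- cells.

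The remaining lists, in the order subsets, NMO CD11c- against control, NMO CD11c+ against control, had these medians and camera adjusted p. Cholesterol biosynthesis had 0.02 (0.959), -0.15 (0.41) and -0.08 (0.596). Glycolysis had 0.26 (0.00621, 0.505 with an estimated correlation), 0.04 (0.756) and 0.28 (0.0301, 0.531 with an estimated correlation). Without CD11c+ replicate 1 the glycolysis calls are lost (0.517 and 0.445), and the latter also without control replicate 3 (0.0599). Oxidative phosphorylation had 0.09 (0.115), 0.10 (0.167) and 0.18 (0.0301, 0.512 with an estimated correlation), lost without CD11c+ replicate 1 (0.148) or control replicate 3 (0.0833). Mitochondrially encoded genes had 0.13 (0.286, or 0.00369 without CD11c+ replicate 1), 0.20 (0.167) and 0.31 (0.0598), with the last called without CD11c+ replicate 1 (0.00134) or control replicate 3 (0.0185). Immediate-early genes had 0.75 between the subsets (0.0177, 0.76 with an estimated correlation). That is -0.85 without CD11c+ replicate 2 and not called without NMO CD11c- replicate 1 (0.512). They had -0.37 in CD11c+ cells against controls (0.0301, 0.635 with an estimated correlation). That is 0.42 (0.423) without CD11c+ replicate 1 and 0.11 (0.154) without control replicate 1. The score of these genes was 7.13 and 9.74 in the CD11c+ libraries, so no direction is claimed for them. Between the subsets complement had 0.04 (0.802) and lipid uptake 0.21 (0.107, or 0.0495 without NMO CD11c- replicate 1). Cytokines there had 0.43 (0.0256, 0.735 with an estimated correlation), or -0.60 without CD11c+ replicate 2 and adjusted p = 0.148 without NMO CD11c- replicate 1.

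Among markers of other cells, border-associated macrophage, monocyte and neutrophil genes were higher as lists in NMO CD11c- cells than in controls, by camera with the preset correlation. With an estimated correlation the adjusted p = 0.355, 0.017 and 0.136 in that order, so only the monocyte list stays called (median 1.77, adjusted p = 5.25e-13). Border-associated macrophage genes had 0.07 (0.802, or -0.50 and 0.0152 without CD11c+ replicate 1), 0.61 (0.000195, 0.355 with an estimated correlation) and 0.34 (0.018, 0.531 with an estimated correlation). The last is -0.26 (0.423) without CD11c+ replicate 1 and not called without control replicate 1 (0.0782). Siglec1, an interferon-responsive lectin gene, was at 49.3 against 13.2 CPM in NMO CD11c- and control cells. Dendritic cell genes had 0.07 (0.802), 0.33 (0.104, or 0.0278 without control replicate 2) and 0.41 (0.134). Flt3 was at 8.18, 5.92 and 1.70 CPM in CD11c+, CD11c- and control cells. Astrocyte genes had 0.07 (0.834), 0.42 (0.41) and 0.37 (0.672). Oligodendrocyte genes had 0.21 (0.398), 0.02 (0.585) and 0.07 (0.768), with Mbp at 53.5, 52.5 and 50.9 CPM. Endothelial genes had 0.46 (0.0567, or 0.0426 without control replicate 2), -0.23 (0.273) and -0.04 (0.571). Monocyte genes in CD11c+ cells against controls had a median of 0.27 (0.537). Neutrophil genes in NMO CD11c- cells against controls had 1.86 (7.22e-08, 0.136 with an estimated correlation), with 2 of 10 higher, 9 when adjusted over the list alone. That count was 6, 6, 0, 0, 5, 0, 0 and 4 with libraries left out in the same order. Growth factor genes in NMO CD11c- cells against controls had 3 higher and 1 lower of 16 (0.22, 0.108). They had 6 higher without either CD11c+ library and 1 higher without any other library, and none lower without control replicate 1 or 2. T cell, B cell, NK cell, neuron and erythrocyte markers and the sex-linked list had under 3 tested members and no list test. Ighm, a B cell marker, was at 374, 388 and 409 CPM and Xist at 1162, 1503 and 1136 CPM, so female cells are present in every group.

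NMO CD11c- replicate 2 was above the other replicates of its group in the neutrophil granule genes Ngp, at 2688 CPM (647 and 429 in the others), and Camp, at 735 (170.0 and 111), and in Chil3, at 866 (197 and 114). Mmp8 (44.7 against 56.4 and 40.0) and Retnlg (26.1 against 40.4 and 30.6) were not higher there. The cause was not tested.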
